A study of Saccharomyces cerevisiae with 16 samples.

How the data were processed

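The series holds 16 libraries of the budding yeast strain BY4741 and of deletions of CAN1, RPL22A and TOR1 in it, grown in rich medium to an optical density of 0.5. Per the labels, footprints were made by RNase I digestion and isolation of the 80S fraction, with cycloheximide in the lysis buffer, and mRNA came from aliquots of the same lysates by poly(A) selection and alkaline hydrolysis. Groups were taken from the sample labels: 3 wild-type, 3 can1, 2 rpl22a and 2 tor1 footprint libraries, and 2 wild-type, 2 can1, 1 rpl22a and 1 tor1 mRNA libraries. The labels do not say whether replicates are separate cultures, so p-values measure only the spread between these samples.

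The authors aligned reads with Bowtie 1.1.2 to genome build R64, and the deposited files list, per the file headers, an open reading frame name, a length and RPKM (reads per kilobase of that length per 1e6 reads). How reads with several matches were assigned is not given in the sources used here. The listed length was the coding length less 100 bases for 5408 of 5456 single genes. Of 5574 listed features, 116 are merged groups of near-identical genes (335 names); levels of such genes, and of genes overlapping another on either strand, are uncertain. The annotation writes bifunctional genes without a comma (ARG56, DUR12), and that spelling is used.

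Values of few reads fall on even steps, so library totals and read numbers were recovered from them (tolerance 0.05). In 13 libraries 1 step fitted all values of up to 50 reads. Wild-type footprint replicate 1, wild-type mRNA replicate 2 and the rpl22a mRNA library were instead fitted by the mean RPKM of 2 runs of different depth. Read numbers given for these libraries are the mean level times the summed total, rounded, and so are approximate. The recovery was tested on simulated tables, where totals of 16 of 16 libraries came within 1 percent. Those tables were built as the recovery assumes. The test thus checks the arithmetic and not whether the deposited values follow that model. Listed features held between 76.4 and 81.7% of footprint reads and between 54.4 and 61.4% of mRNA reads. Between 299 and 463 features had no reads in a footprint library and between 119 and 180 in an mRNA library.

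Because the files hold RPKM and not read counts, the planned count test was replaced by limma 3.58.1 (with statmod 1.5.0 in R 4.3.3) on log2(scaled RPKM + 1), with trended and robust moderation of the variance. Scaling factors were trimmed means of M values (30% trimmed on fold, 5% on level), computed within each assay on the recovered reads. Genes were tested when they reached the level of 10 reads in the median library in at least 2 footprint or 1 mRNA libraries, with at least 15 reads in total. Translational efficiency was the interaction of assay and strain over all 16 libraries. That fit treated footprint and mRNA libraries as independent, although both came from the same lysates. The check of replicate numbers below compared libraries within an assay only. Calls are at a Benjamini-Hochberg adjusted p under 0.05, and errors after ± are standard errors, or standard deviations where levels are given. The mRNA variances were pooled almost fully over genes (median degrees of freedom 10598, against 11.2 for footprints). Most mRNA p-values thus assume 1 spread for genes of like level, while robust moderation lets outlying genes keep more of their own.

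Gene lists (34, of which 33 had enough footprint data) were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Within a list, counts are given over all genes and adjusted over the list alone. The 16 chromosome sets gave 0 calls in camera in all 12 comparisons. Comparisons that share wild-type libraries were set against simulated unchanged groups (100 draws) and against separate wild-type libraries. The coding-length trend is a lowess line (span 0.5) per library over genes of at least 10 RPKM.

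The groups, the comparisons, the gene lists and the rule for named genes were fixed before the data were examined. The rule names the deleted gene with its paralogs, neighbours, the strain's markers and GCN4. It adds up to 10 genes per direction with the largest fold among those past the threshold, with at least 10 reads per 1e6 in the higher group and no overlap between libraries. It also adds up to 4 members with the smallest p of each list past the camera threshold. The results of 1 gene are not reported here. The text prints subsets in that order and says where a gene was chosen after its values were seen.

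Whether replicate numbers pair libraries was checked on deviations from strain means over 3591 genes. Same-number wild-type and can1 footprint libraries correlated at 0.67, 0.27 and 0.42, wild-type and rpl22a at −0.33 and −0.10, and wild-type and tor1 at −0.01 and 0.01. The 2 mRNA pairs correlated at 0.10 over 3857 genes. This is 1 value and not 2, since the deviations of 2 libraries from their mean are equal and opposite. A replicate block over all numbered libraries had been chosen beforehand as a second setting; a block for wild-type and can1 libraries alone was added after seeing the data.

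Alternatives covered the scaling, the filter, the pseudocount, robust moderation, voom on the recovered reads, the samples in the fit, replicate blocks, removal of the length trend, a 2-fold minimum and leaving out each replicate. On simulated data of the same depth and spread, with 200 changed genes per strain and assay, 95.2% of 2-fold changes were called in can1 footprints, 79.1% in rpl22a footprints, 66.2% in can1 mRNA and 58.6% in rpl22a mRNA, with 0 wrong signs and between 1.42 and 6.84% false calls. The simulated noise was independent between genes, without length trends or a shared replicate structure. With 200 changed genes the adjusted threshold is also easier to pass than where few genes change. The simulated shares may thus overstate what the real comparisons with few calls could find. Figures and read recovery used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.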

Results

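Ribosome footprints and mRNA were sequenced from exponentially growing budding yeast (*Saccharomyces cerevisiae*, BY4741). There were 4 strains: wild type and strains lacking CAN1 (the plasma membrane arginine permease), RPL22A (a protein of the large ribosomal subunit) or TOR1 (a kinase of the TORC1 growth-signalling complex). Footprints, the pieces of mRNA that ribosomes protect from nuclease, came from 3 wild-type, 3 can1, 2 rpl22a and 2 tor1 libraries. The mRNA set held 2 wild-type, 2 can1, 1 rpl22a and 1 tor1 libraries. Library totals, read from the steps of the deposited values, were, in units of 1e6 reads, 8.56, 5.16 and 2.52 for wild-type footprints and 8.70, 4.75 and 3.42 for can1 footprints. They were 6.93 and 3.42 for rpl22a and 3.36 and 5.81 for tor1 footprints. For mRNA the totals were 7.65 and 26.6 in wild type, 12.1 and 12.9 in can1, 23.1 in rpl22a and 9.82 in tor1. All levels below are deposited RPKM after scaling between libraries, and fold changes are on a log2(RPKM + 1) scale, which understates the change of genes at low levels. Positions refer to genome build R64.

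Each deletion was seen in its own libraries. Read numbers are approximate for wild-type footprint replicate 1, wild-type mRNA replicate 2 and the rpl22a mRNA library. CAN1 (YEL063C, chromosome V, 31694 to 33466) had between 208 and 582 footprint reads in the 3 wild-type libraries and 1, 2 and 1 in the can1 libraries. In mRNA it had 147 and 619 reads in wild type and 0 and 3 in can1. Footprint reads of CAN1 were 921 and 398 in rpl22a and 247 and 420 in tor1, with 1171 and 206 mRNA reads. RPL22A (YLR061W, chromosome XII, 263194 to 263948) had between 1883 and 7862 footprint reads in wild type against 5 and 17 in rpl22a, and 85 mRNA reads in the rpl22a library against 14181 and 31274. RPL22A has a close copy, RPL22B, and the few reads left could not be assigned with certainty. TOR1 (YJR066W, chromosome X, 559416 to 566828) had between 129 and 285 footprint reads in wild type, 2 and 1 in tor1, and 0 mRNA reads in tor1 against 178 and 662 in wild type. The markers that BY4741 lacks, LEU2 and URA3, had 0 reads in every library, and MET17 had 0 except for 1 read in tor1 footprint replicate 2. Reads of HIS3, which BY4741 also lacks in part, were present in every library.

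The first comparison asked which genes ribosomes occupied more or less when the arginine permease was missing. Of 9 genes that make arginine 7 rose in can1 footprints. ARG3, ornithine carbamoyltransferase (YJL088W, chromosome X, 268799 to 269815), rose from a mean of 4.13 to 72.6 RPKM, a log2 fold change of 3.94 ± 0.28 (SE, n = 3 and 3, adjusted p = 2.31e-05). ARG1, argininosuccinate synthetase (YOL058W, chromosome XV, 219211 to 220473), rose by 3.39 ± 0.24 (adjusted p = 1.99e-05) and ARG56, which carries 2 steps of ornithine synthesis (YER069W, chromosome V, 295410 to 298001), by 2.79 ± 0.17 (adjusted p = 1.05e-05). ARG8, acetylornithine aminotransferase (YOL140W, chromosome XV, 58759 to 60030), rose by 2.76 ± 0.22 (adjusted p = 4.45e-05), and CPA1, of the arginine-specific carbamoyl phosphate synthetase (YOR303W, chromosome XV, 882899 to 884134), by 2.25 ± 0.15 (adjusted p = 1.79e-05). ARG4, argininosuccinate lyase (YHR018C, chromosome VIII, 140011 to 141402), rose by 0.74 ± 0.11 (adjusted p = 0.0205). Among genes of arginine breakdown, DUR12 and CAR2 fell and CAR1 did not pass. DUR12, urea amidolyase (YBR208C, chromosome II, 636703 to 642210), changed by −1.84 ± 0.27 (adjusted p = 0.0131), and CAR2, ornithine transaminase (YLR438W, chromosome XII, 1012501 to 1013775), by −1.73 ± 0.21 (adjusted p = 0.00241). For each of these 8 genes all 3 can1 libraries lay beyond all 3 wild-type libraries, as the rule for naming them required.

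Of 4882 genes tested in can1 footprints, 7 were higher and 4 lower than in wild type. The higher genes include the 6 arginine genes above, and the lower ones are CAN1, DUR12, CAR2 and MTE1. MTE1, a DNA repair and telomere protein named here after its values were seen, changed by −0.94 ± 0.15 (adjusted p = 0.0285) in 3 of 3 libraries, at about 3 RPKM. That call was lost when any one of the 6 libraries was left out, with adjusted p between 0.0594 and 0.226. ARG4 lost its call without can1 replicate 3 (adjusted p = 0.0965), wild-type replicate 2 (0.145) or wild-type replicate 3 (0.0775), and with the libraries of the 2 strains alone (0.133). DUR12 lost it without can1 replicate 2 (adjusted p = 0.0585) or can1 replicate 3 (0.065). With the replicate number of wild-type and can1 libraries as a block, 11 genes were higher and 6 lower, and 10 of the 11 genes called without the block were among these 17. With that block and the libraries of the 2 strains alone 13 were higher and 16 lower, and 10 of the 11 were among these 29. GCN4, which encodes the activator of amino acid synthesis genes, stood at 0.53 ± 0.23 (adjusted p = 0.999), and LYP1, the lysine permease related to CAN1, at 0.23 ± 0.19 (adjusted p = 0.999). ALP1, the closest relative of CAN1, had between 0 and 2 footprint reads per library, too few to test.

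**Figure D1:**
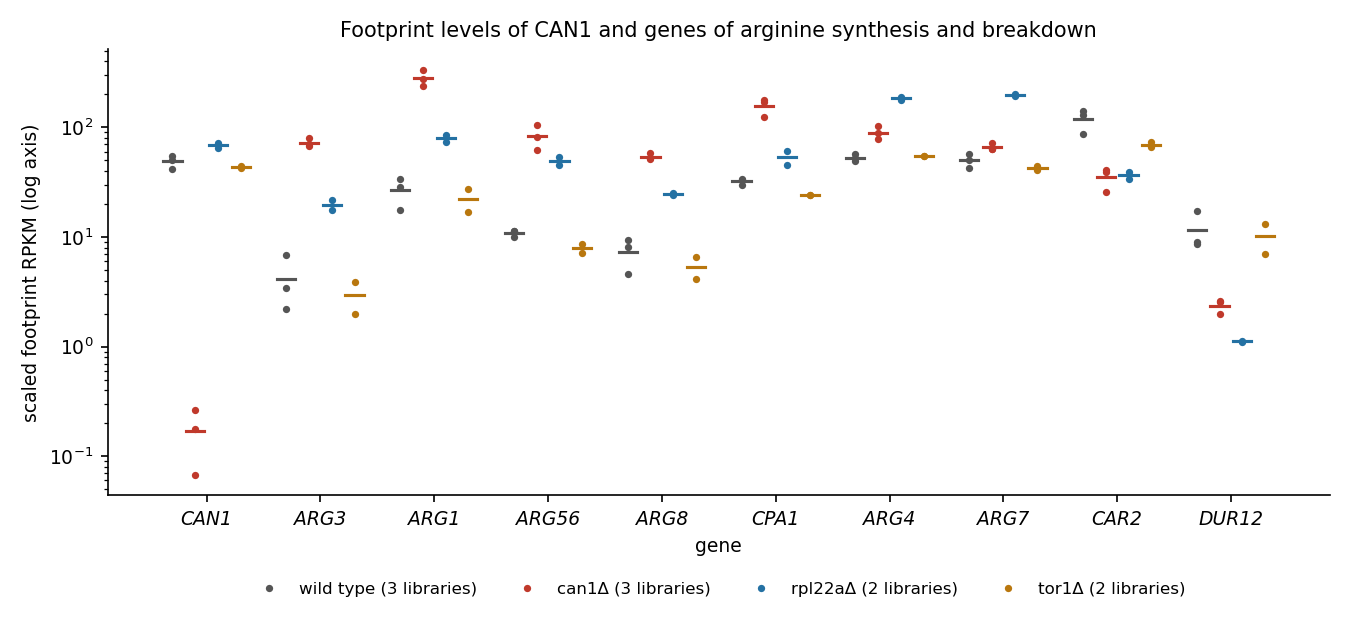
Scaled footprint level (RPKM, log axis) of CAN1, 7 arginine synthesis genes and 2 arginine catabolism genes in each strain, with points for libraries and bars for group means. ARG3 lies at a mean of 72.6 RPKM in can1, 19.7 in rpl22a, 2.95 in tor1 and 4.13 in wild type.

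Lists of genes fixed before the data were examined gave the same picture of can1 footprints. Of 9 arginine synthesis genes 7 rose, 8 when adjusted over the list alone, with a median log2 fold change of 2.25, and the list kept its call with an estimated correlation between genes (adjusted p = 0.0135). The members that did not pass over all genes, named after their values were seen, were ARG7 at 0.42 ± 0.12 (adjusted p = 0.587) and ARG2 at −0.10 ± 0.14 (adjusted p = 0.999). Of 39 targets of Gcn4 6 rose (10 adjusted over the list alone), all 6 of them arginine genes, with a list median of 0.17 (adjusted p = 0.0393 with an estimated correlation). Among genes repressed by good nitrogen sources, DUR12 and CAR2 fell, and CAR1, arginase, joined them when adjusted over the list alone (−0.62 ± 0.17); it passed over all genes with the block and the 2 strains alone (adjusted p = 0.0398). That list had a median of −0.14 over 11 genes (adjusted p = 0.342 with an estimated correlation). Branched-chain amino acid synthesis had a median of 0.19 with 0 of 10 genes past the limma threshold. When adjusted over the list alone 4 passed, BAT1 at 0.60, BAT2 at 0.87, LEU1 at 0.59 and LEU4 at 0.39 (adjusted p for the list = 0.34 with an estimated correlation). BAT1 passed over all genes without wild-type replicate 3 (adjusted p = 0.0184), and with the block for wild type and can1 both BAT1 (0.0319) and BAT2 (0.0416) did.

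Stress genes were of particular interest, since the series title links loss of CAN1 to their translation. Of 36 general stress genes controlled by Msn2 and Msn4, limma called 0 in can1 footprints and 1 lower when adjusted over the list alone, SSA4 (an Hsp70 chaperone) at −0.95 ± 0.17 (adjusted p = 0.0789 over all genes). The median of that list was 0.04, with 21 of 36 genes above 0, and the list did not pass (camera adjusted p = 0.241, or 0.755 with an estimated correlation). The median was −0.03 without can1 replicate 3. For 20 chaperone genes controlled by Hsf1 the median was −0.23, with 0 genes past the threshold over all genes and 4 lower when adjusted over the list alone. These were SSA4, STI1 at −0.42, HCH1 at −0.59 and YDJ1 at −0.29 (adjusted p for the list = 0.123 with an estimated correlation). HCH1 passed over all genes with the block and the 2 strains alone (adjusted p = 0.0085). Trehalose and glycogen genes, whose products are reserve and stress carbohydrates, had a median of 0.19 over 18 genes with 0 past the threshold. GSY2 at 0.88 ± 0.24 and GSY1 at 1.05 ± 0.30, the glycogen synthases, passed when adjusted over the list alone (adjusted p for the list = 0.342 with an estimated correlation). The median over 95 cytosolic ribosomal protein genes was −0.16 with 0 past the threshold (adjusted p = 0.53 with an estimated correlation). Over all genes 234 had an unadjusted p under 0.05, against 244.1 that chance alone would give. That fit had no replicate block, although same-number wild-type and can1 libraries correlated, so the count does not show that no further genes changed. At the preset correlation camera called 16 of 33 lists, 9 higher and 7 lower, and 10 without can1 replicate 2. With an estimated correlation it called 2, the arginine and Gcn4 lists.

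Far more genes were called in rpl22a footprints, a group of 2 libraries. The paralog RPL22B (YFL034C-A, chromosome VI, 64243 to 64932) rose from 267 to 1290 RPKM in rpl22a footprints, a log2 fold change of 2.27 ± 0.16 (SE, n = 2 and 3, adjusted p = 1.9e-05). Of 9 arginine synthesis genes 8 rose (adjusted p for the list = 0.104 with an estimated correlation). ARG3 rose by 2.11 ± 0.32 (adjusted p = 0.00126), ARG56 by 2.08 ± 0.19 (adjusted p = 6.29e-05), ARG7, ornithine acetyltransferase (YMR062C, chromosome XIII, 395054 to 396379), by 1.97 ± 0.14 (adjusted p = 1.9e-05) and ARG4 by 1.78 ± 0.13 (adjusted p = 1.9e-05). Of 12 phosphate regulon genes 11 fell (adjusted p for the list = 0.136 with an estimated correlation). PHO89, a phosphate transporter, stood at −2.85 ± 0.46 (adjusted p = 0.00265), PHO84, the main high-affinity transporter, at −2.24 ± 0.32 (adjusted p = 0.00125), and VTC3, of the polyphosphate polymerase, at −1.99 ± 0.24 (adjusted p = 0.000295). In between lay DUR12 at −2.51 ± 0.30 (adjusted p = 0.000295) and TIR1, a cell wall mannoprotein, at −2.41 ± 0.22 (adjusted p = 5.5e-05). RPP2B, an acidic protein of the ribosomal stalk, fell by 1.93 ± 0.16 on the log2 scale (adjusted p = 2.97e-05). HIS3 reads rose by 1.56 ± 0.12 (adjusted p = 2.38e-05). Both rpl22a libraries lay beyond all 3 wild-type libraries for every gene of this paragraph, as the naming rule required of genes chosen by fold.

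In all, 429 genes were higher and 498 lower in rpl22a footprints. Without scaling between libraries beyond the deposited RPKM the median of all genes moved by 0.17 and the split became 886 higher and 293 lower, so the balance of directions depended on the scaling. The count was 331 without rpl22a replicate 2 and 532 without rpl22a replicate 1. Replicate 2 had 76.4% of its reads in listed features, the lowest share of any footprint library, against 80.6% in replicate 1. GCN4 stood at 0.61 ± 0.25 (adjusted p = 0.112), higher than all wild-type libraries in 1 of 2 libraries, and passed without wild-type replicate 2 (0.88, adjusted p = 0.0212) or with the deposited scaling (0.79, adjusted p = 0.0345).

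Of 39 Gcn4 targets 25 rose in rpl22a footprints and 0 fell (27 and 1 when adjusted over the list alone), with a median of 0.51 (adjusted p = 0.104 with an estimated correlation). The arginine list had 8 of 9 genes higher, 8 when adjusted over the list alone, and a median of 1.78 (adjusted p = 0.104 with an estimated correlation); ARG2, which did not pass, stood at 0.27 ± 0.16. Of 10 branched-chain genes 7 rose, 7 also when adjusted over the list alone (adjusted p for the list = 0.187 with an estimated correlation). Among these were LEU4, isopropylmalate synthase, at 1.24 ± 0.14 and ILV6, of acetolactate synthase, at 1.23 ± 0.11. LYS1, saccharopine dehydrogenase, rose by 1.31 ± 0.13, and HIS1, the first enzyme of histidine synthesis, by 0.94 ± 0.10.

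Other lists had members that fell in rpl22a footprints, and none of these lists kept its call with an estimated correlation. The phosphate regulon had 11 of 12 genes lower, 12 when adjusted over the list alone, with VTC4 at −1.38 ± 0.14 (adjusted p for the list = 0.136 with an estimated correlation). Of 20 Hsf1 chaperone genes 12 fell (14 when adjusted over the list alone), with a median of −0.76 (adjusted p = 0.104 with an estimated correlation); HSP60, the mitochondrial chaperonin, stood at −1.54 ± 0.10 and STI1, an Hsp90 co-chaperone, at −1.17 ± 0.12. Of 36 Msn2/Msn4 stress genes 11 fell and 0 rose, 13 when adjusted over the list alone, including HSP26, a small heat shock protein, at −2.13 ± 0.26 and SSA4 at −1.86 ± 0.19 (adjusted p for the list = 0.269 with an estimated correlation). Purine synthesis had 9 genes lower and 1 higher of 13 (10 and 1 when adjusted over the list alone), with ADE17 at −1.66 ± 0.10 and ADE13 at −1.29 ± 0.11 (adjusted p for the list = 0.104 with an estimated correlation). Glycolysis had 12 of 15 lower (13 when adjusted over the list alone), with HXK2, the main hexokinase, at −1.39 ± 0.12 (adjusted p for the list = 0.149 with an estimated correlation). Of 20 genes of the tricarboxylic acid cycle 11 fell and 1 rose (12 and 1 when adjusted over the list alone), with LPD1 at −0.96 ± 0.10 and CIT1, citrate synthase, at −1.32 ± 0.15 (adjusted p for the list = 0.112 with an estimated correlation). Sulfur amino acid synthesis had 7 of 16 lower (9 when adjusted over the list alone), with SAM2, which makes S-adenosylmethionine, at −1.59 ± 0.14 (adjusted p for the list = 0.15 with an estimated correlation). Of 95 cytosolic ribosomal protein genes 4 were higher and 9 lower, counts that did not change when adjusted over the list alone. Their list did not pass (camera adjusted p = 0.653); its median was 0.10, its mean −0.02, and with the length trend of each library removed the median was −0.09. At the preset correlation camera called 22 of 33 lists (7 higher, 15 lower) and with an estimated correlation 0, while fry, which asks only whether a list moves one way, called 23.

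**Figure D2:**
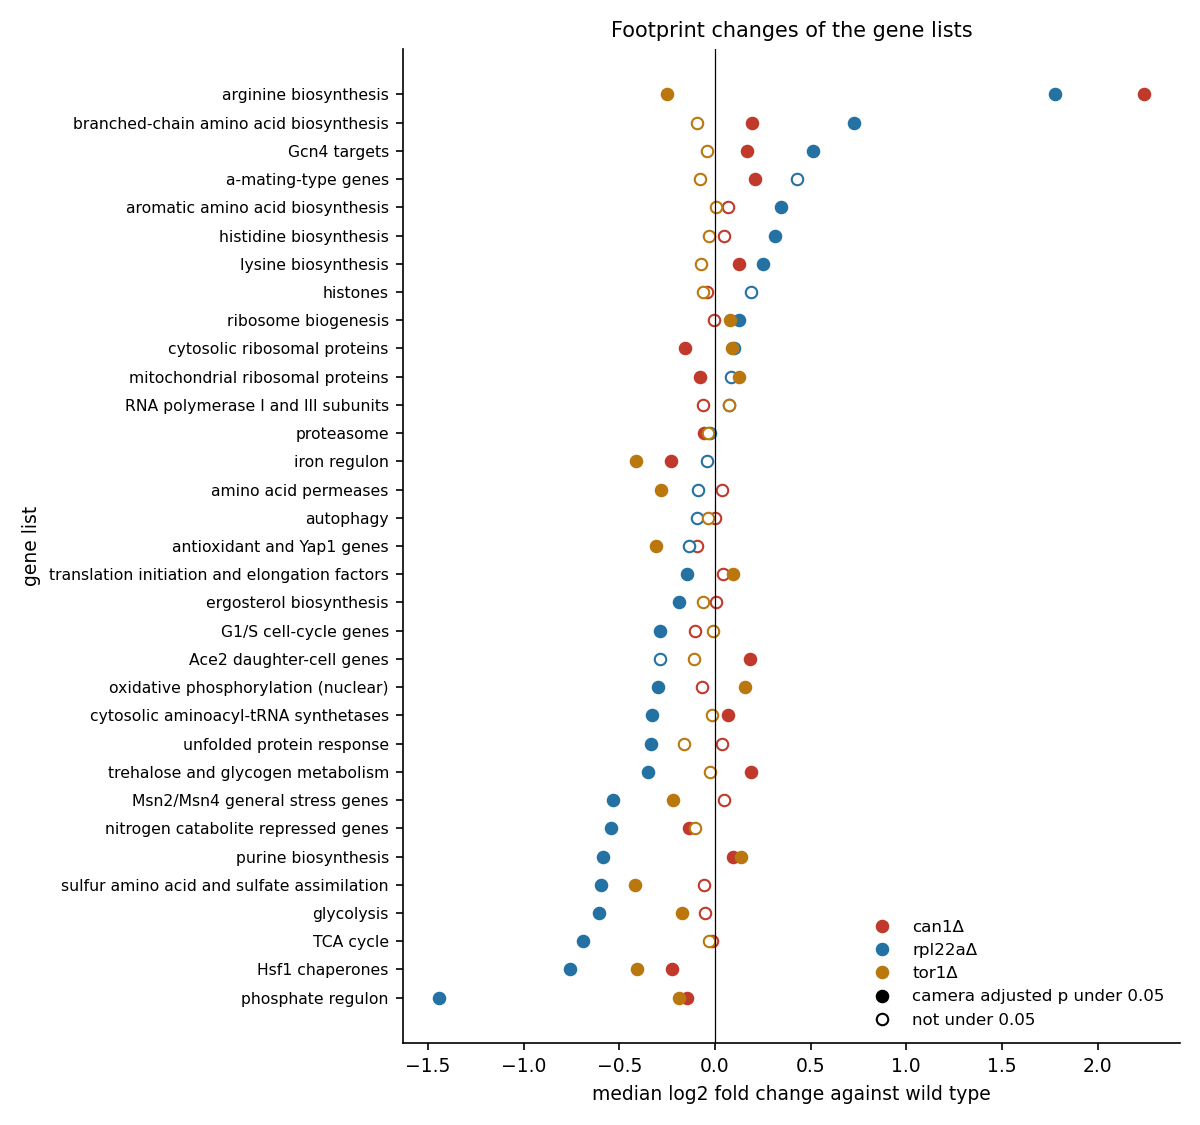
Median log2 fold change against wild type (x axis) of 33 gene lists (y axis) in can1, rpl22a and tor1 footprints, filled where the camera adjusted p at the preset correlation was under 0.05. The arginine list lies at 2.25 in can1, 1.78 in rpl22a and −0.25 in tor1.

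Short genes had higher and long genes lower footprint levels in rpl22a. Among 642 genes with a coding length under 500 bases as listed the median log2 fold change was 0.36, with 137 higher and 22 lower; among 1098 genes of 2000 bases or more it was −0.18, with 16 higher and 172 lower. Across 4787 genes, which are not independent replicates, the Spearman correlation of fold change with length was −0.42, against 0.24 in can1 and −0.24 in tor1. The long minus short difference was −0.23 and −0.58 in the rpl22a libraries, between −0.13 and 0.34 in wild type, between 0.02 and 0.44 in can1, and −0.05 and −0.02 in tor1. These trends ran alongside the amino acid, chaperone and ribosomal protein results above. In rpl22a footprints 8 arginine genes stayed past the threshold after the trend was removed, a trend small beside the median rise of their list.

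**Figure D3:**
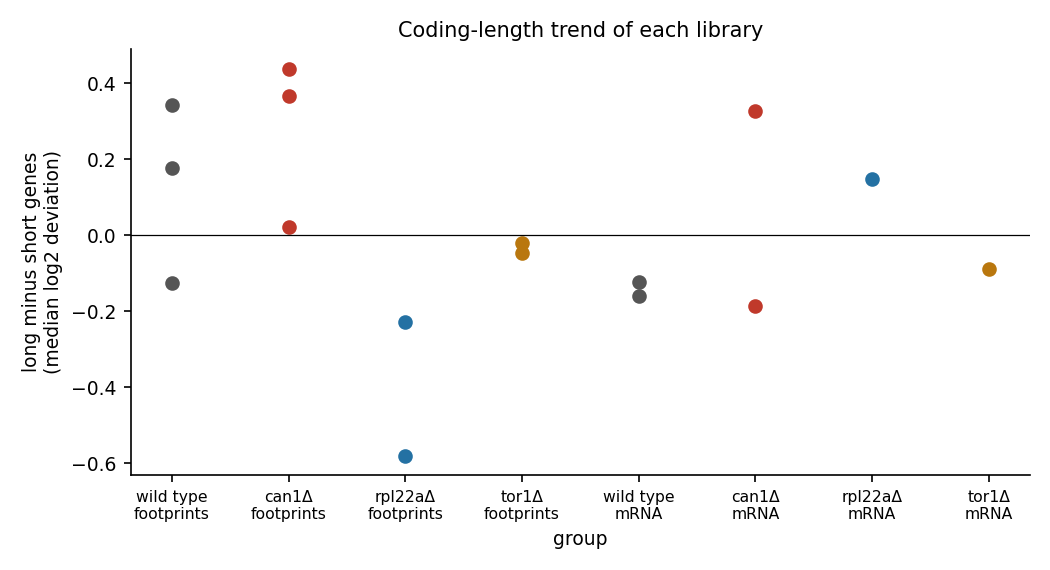
Median log2 deviation of long genes less that of short genes (y axis) in each library, with 1 point per library and the footprint and mRNA groups along the x axis. The rpl22a footprint libraries lie at −0.23 and −0.58, and the other footprint libraries between −0.13 and 0.44.

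Few genes passed in tor1 footprints. Apart from TOR1, 1 gene passed: HEM13, coproporphyrinogen oxidase of heme synthesis (YDR044W, chromosome IV, 546642 to 547628), rose from 108 to 251 RPKM, a log2 fold change of 1.17 ± 0.17 (SE, n = 2 and 3, adjusted p = 0.0495), higher in 2 of 2 libraries. That call was lost without tor1 replicate 1 (0.86, adjusted p = 0.338) and without wild-type replicate 1 (0.107), 2 (0.131) or 3 (0.169). Without tor1 replicate 2, 9 genes were called. Over all 4882 genes 357 had an unadjusted p under 0.05, against 244.1 that chance alone would give. The iron regulon had a median of −0.41 over 24 genes with 0 past the threshold. ARN1, a siderophore transporter, at −1.28 ± 0.30 and FTR1, the iron permease, at −0.42 ± 0.11 passed when adjusted over the list alone (adjusted p for the list = 0.159 with an estimated correlation). Hsf1 chaperone genes had a median of −0.41 with 0 past the threshold and 8 lower when adjusted over the list alone, HSP60 at −0.47 ± 0.10 among them. Sulfur amino acid synthesis had a median of −0.42 with 0 past the threshold and 6 lower when adjusted over the list alone, with MET6, methionine synthase, at −0.66 ± 0.13. For both lists the adjusted p was 0.159 with an estimated correlation. At the preset correlation camera called 15 of 33 lists, 6 higher and 9 lower, and with an estimated correlation 0. The lists described above all had medians below 0. In simulated data of the same depth and spread 90.9% of genes changed 2-fold were called in this comparison, and 29.6% of those changed 1.5-fold. There 200 genes were changed, which makes the adjusted threshold easier to pass than with the 2 genes called here. These shares may thus be too high for the real comparison.

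The deletion strains were also compared directly, which leaves the wild-type libraries out of the difference. Between can1 and rpl22a footprints 608 genes were higher and 554 lower in can1. With the deposited scaling the median of all genes moved by −0.14 and the split became 364 and 857; 387 genes were called without rpl22a replicate 2, 676 without rpl22a replicate 1 and 686 without can1 replicate 3. Higher in can1 were PTR2, a peptide transporter, by 2.84 ± 0.35 (SE, n = 3 and 2, adjusted p = 0.000668), TIR1 by 2.54 ± 0.22 (adjusted p = 4.53e-05), MDH2, cytosolic malate dehydrogenase, by 2.27 ± 0.21 (adjusted p = 7.56e-05), GLN1, glutamine synthetase, by 2.21 ± 0.16 (adjusted p = 1.78e-05; 1297 against 278 RPKM) and ARG3 by 1.83 ± 0.32 (adjusted p = 0.00278). ISU2, an iron-sulfur scaffold protein, was lower at −1.67 ± 0.16 (adjusted p = 7.61e-05) and ARG7 at −1.55 ± 0.14 (adjusted p = 4.72e-05). All 3 can1 libraries lay beyond both rpl22a libraries for each of these genes, as the naming rule required of genes chosen by fold.

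The arginine genes thus moved by different amounts in the 2 strains. Of 9, 5 were higher and 3 lower in can1 than in rpl22a, and 5 and 4 when adjusted over the list alone. The lower ones include ARG7 and ARG4, which stood at −1.04 ± 0.13 (adjusted p = 0.000398). CPA1, named like ARG4 after its values were seen, was higher at 1.55 ± 0.17 (adjusted p = 0.00019). Of 39 Gcn4 targets 17 were lower and 6 higher in can1 (19 and 6 when adjusted over the list alone), with a median of −0.35 (adjusted p = 0.284 with an estimated correlation). LYS1 at −1.15 ± 0.13, ILV6 at −1.07 ± 0.11 and HIS1 at −0.94 ± 0.10 were lower in can1. Of 36 Msn2/Msn4 stress genes 16 were higher in can1 than in rpl22a (20 against 1 lower when adjusted over the list alone), with HSP26 at 1.92 ± 0.26. Of 20 Hsf1 chaperone genes 11 were higher and 1 lower (13 and 1 when adjusted over the list alone), with HSP60 at 1.31 ± 0.10. Both lists lost their call with an estimated correlation (adjusted p = 0.284 each). ADE17 was higher at 1.74 ± 0.10. At the preset correlation camera called 22 of 33 lists (16 higher, 6 lower in can1), all with adjusted p of at least 0.284 with an estimated correlation.

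Between can1 and tor1 footprints 8 genes were higher and 1 lower in can1. ARG3 at 4.26 ± 0.32 (SE, n = 3 and 2, adjusted p = 3.26e-05), ARG1 at 3.64 ± 0.26, ARG56 at 3.21 ± 0.19, ARG8 at 3.14 ± 0.24 and CPA1 at 2.65 ± 0.17 were higher, as was TOR1, and CAN1 was lower. Also higher was ARO10, a decarboxylase of amino acid breakdown, at 1.56 ± 0.24 (adjusted p = 0.0255), which lost its call without can1 replicate 2 (0.107), can1 replicate 3 (0.0838) or tor1 replicate 2 (0.276). The arginine list passed with a median of 2.65 (adjusted p = 0.0441 with an estimated correlation), 1 of 21 lists that passed at the preset correlation. Between rpl22a and tor1 footprints 334 genes were higher and 386 lower in rpl22a, and with the deposited scaling, which moved the median by 0.12, 565 and 255. Fold changes followed coding length here too (Spearman correlation −0.29). Leaving out 1 library gave 412 without rpl22a replicate 1, 284 without rpl22a replicate 2, 239 without tor1 replicate 1 and 376 without tor1 replicate 2. ARG56 was higher by 2.50 ± 0.21 (SE, n = 2 and 2, adjusted p = 6.38e-05), ARG3 by 2.43 ± 0.35 and ARG7 by 2.18 ± 0.15. TIR1 stood at −2.88 ± 0.24 (adjusted p = 5.6e-05), DUR12 at −2.34 ± 0.33 and ADE17 at −1.89 ± 0.11. Camera called 22 lists at the preset correlation and 0 with an estimated one. Of 39 Gcn4 targets 24 were higher in rpl22a (28 when adjusted over the list alone), with a median of 0.60 (adjusted p = 0.0952 with an estimated correlation).

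The 7 genes higher in can1 footprints were all higher in rpl22a too, where independent lists of these sizes would share 0.615, a value that makes no allowance for the shared wild-type libraries. Unchanged groups simulated against 1 shared set of simulated wild-type libraries had a mean of 0 genes in common. They have almost no calls to share and so set no level for comparison. Of the 4 genes lower in can1, CAR2 and DUR12 were lower in rpl22a (independent lists, 0.408). Across all 4882 genes, which are not independent replicates, the Pearson correlation of fold changes was 0.103 for can1 and rpl22a, 0.175 for can1 and tor1 and 0.275 for rpl22a and tor1. For simulated unchanged groups, deviations from strain means were shuffled over all footprint libraries. The simulated strains thus shared a simulated wild-type set, not the deposited one. They gave mean correlations of 0.425, 0.390 and 0.398 with standard deviations of 0.312, 0.310 and 0.334. Of 100 draws 82, 77 and 68 lay at or above the observed values. Within rpl22a and within tor1 the deviations are equal and opposite, so the draws do not give the spread for the deposited wild-type libraries. Covariances were 0.0119, 0.0108 and 0.0341, against simulated 0.0199, 0.0177 and 0.0199. With separate wild-type libraries for each strain the mean correlations were −0.0378 (range −0.263 to 0.145), −0.0701 (−0.363 to 0.136) and 0.0899 (−0.0673 to 0.174). With shared wild-type libraries the Spearman correlations were 0.00873, 0.168 and 0.275. The Pearson correlations with the length trend removed were 0.184, 0.234 and 0.206.

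The mRNA libraries asked which of these changes lay in transcript levels. In can1 mRNA ARG3 rose from 4.25 to 52.1 RPKM, a log2 fold change of 3.41 ± 0.22 (SE, n = 2 and 2, adjusted p = 1.61e-50), ARG56 rose by 1.84 ± 0.21 (adjusted p = 8.18e-15), and CAR2 fell by 1.98 ± 0.25 on the log2 scale (adjusted p = 1.95e-12). These 3 genes kept their calls with each library left out in turn. ARG1 rose by 2.84 ± 0.27 (adjusted p = 1.12e-11), ARG8 by 1.11 ± 0.23 (adjusted p = 0.000308) and CPA1, named after its values were seen, by 0.88 ± 0.23 (adjusted p = 0.0122). So 5 of 9 arginine genes rose (7 when adjusted over the list alone), with a median of 0.88 (adjusted p = 0.723 with an estimated correlation). All changes of this paragraph were seen in 2 of 2 libraries, as the naming rule required of genes chosen by fold. With 1 library left out the fold changes kept their direction, between 2.06 and 3.61 for ARG1, 0.80 and 1.41 for ARG8 and 0.68 and 1.08 for CPA1, while calls were lost. ARG1 stood at 2.84 and 2.83 without either can1 library, so there the call was lost with no change in size. Without can1 replicate 1 the adjusted p was 0.596 for ARG1, 0.484 for ARG8 and 0.249 for CPA1, and without can1 replicate 2 it was 1, 0.357 and 1. Without wild-type replicate 2 it was 0.187 for ARG8 and 0.309 for CPA1, and without wild-type replicate 1 it was 0.124 for CPA1. ARG1 also lost its call with median-of-ratios factors (0.146), with no filter (0.549) and with the length trend removed (0.733). The very small p-values rest on a spread pooled over genes of like level in few libraries.

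Of 19 trehalose and glycogen genes 4 rose in can1 mRNA (adjusted p for the list = 0.723 with an estimated correlation). GSY1, glycogen synthase, rose by 2.17 ± 0.25 (adjusted p = 1.71e-13), PGM2, phosphoglucomutase, by 1.36 ± 0.23 (adjusted p = 1.2e-06), GLC3, the glycogen branching enzyme, by 1.19 ± 0.24 (adjusted p = 0.000186) and GSY2 by 1.14 ± 0.24 (adjusted p = 0.000308). Adjusted over the list alone 7 rose, with a list median of 0.38. Of 53 Msn2/Msn4 stress genes 10 rose, including PGM2 and HSP42, a small heat shock protein, at 1.56 ± 0.24 (adjusted p = 5.98e-08), and 1 fell, HSP12, a membrane-associated stress protein named after its values were seen, at −1.52 ± 0.22 (adjusted p = 6.36e-09). Adjusted over the list alone 16 rose and 1 fell, with a median of 0.28 (adjusted p = 0.723 with an estimated correlation). All of these were seen in 2 of 2 libraries, and each kept its direction with any 1 library left out, but not its call. Without can1 replicate 2 the log2 fold changes were 1.70 for GSY1, 1.16 for HSP42, 0.86 for PGM2, 0.71 for GLC3, 0.65 for GSY2 and −1.37 for HSP12. There 0 of the 53 stress genes passed and the adjusted p was 0.802 for PGM2, 0.783 for GSY1, 0.339 for HSP12 and 1 for HSP42, GLC3 and GSY2. Without can1 replicate 1 it was 0.123 for GSY1 (2.64) and 0.239 for HSP42 (1.96), and without wild-type replicate 1 it was 0.131 for HSP42 (1.07), 0.332 for GLC3 (1.00) and 0.146 for GSY2 (1.06), with the fold change in brackets. With no filter on low genes GSY1 (0.269), HSP42 (0.137), GLC3 (0.0712) and GSY2 (0.0712) did not pass, nor did GSY1 (0.209) and HSP42 (0.428) with the length trend removed.

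Ribosomal protein mRNA had a median log2 fold change of −0.42 over 95 genes in can1, with 1 gene lower, also when adjusted over the list alone (adjusted p for the list = 0.841 with an estimated correlation). That gene, RPS28B, stood at −1.28 ± 0.33 (adjusted p = 0.0102) in 2 of 2 libraries, and lost its call without can1 replicate 1 (0.592), can1 replicate 2 (1) or wild-type replicate 1 (1), with no filter (0.599), with moderation that was not robust (0.126) and with the length trend removed (0.768). The median was −0.20 with the deposited scaling, −0.18 without can1 replicate 2 and −0.23 without wild-type replicate 1. In its length trend can1 mRNA replicate 2 stood apart. Its long minus short difference was 0.33, against −0.19 in can1 replicate 1 and −0.16 and −0.12 in wild type. Over 5299 genes 48 were higher and 28 lower in can1 mRNA, and with the deposited scaling, which moved the median of all genes by 0.21, 46 and 6. Leaving out 1 library gave 10 without can1 replicate 1, 4 without can1 replicate 2, 15 without wild-type replicate 1 and 157 without wild-type replicate 2. With the replicate number as a block 60 were higher and 78 lower, and 74 genes were shared.

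The rpl22a and tor1 mRNA groups have 1 library each and no spread of their own, so their errors and p-values assume that it varies like the wild-type and can1 libraries. In the single rpl22a mRNA library RPL22B rose by 1.46 ± 0.32 (SE, n = 1 and 2, adjusted p = 0.000593). Of 9 arginine genes 7 rose (adjusted p for the list = 0.529 with an estimated correlation), ARG3 by 1.73 ± 0.27 (adjusted p = 5.81e-08), ARG7 by 1.65 ± 0.29 (adjusted p = 1.82e-06) and ARG56 by 1.63 ± 0.26 (adjusted p = 1.31e-07), as did PCL5, a cyclin that acts on Gcn4, by 1.70 ± 0.29 (adjusted p = 1.82e-06). PHO89 fell by 2.40 ± 0.27 on the log2 scale (adjusted p = 1.94e-15), PHM6, a phosphate-regulated gene, by 2.38 ± 0.27 and HSP26 by 2.35 ± 0.28. Each was seen in the 1 library. Of 41 Gcn4 targets 13 rose (16 when adjusted over the list alone; median 0.54, adjusted p = 0.552 with an estimated correlation), and 8 of 12 phosphate genes fell (11 when adjusted over the list alone; adjusted p = 0.529 with an estimated correlation). Of 53 Msn2/Msn4 genes 13 fell (19 and 1 higher when adjusted over the list alone), with a median of −0.53 (adjusted p = 0.548 with an estimated correlation). In all 67 genes were higher and 124 lower; with the deposited scaling, which moved the median by 0.27, 73 and 44. Without wild-type replicate 1, 78 genes were called, and RPL22B lost its call without wild-type replicate 2 (1.22, adjusted p = 0.092).

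In the single tor1 mRNA library, with the spread of the other groups assumed, 2 genes were called higher and 12 lower. HSP12 fell by 2.84 ± 0.27 on the log2 scale (SE, n = 1 and 2, adjusted p = 1.12e-21), though voom on recovered reads did not call it (adjusted p = 0.0564). FIT3 and FIT2, cell wall mannoproteins that retain siderophore iron, stood at −1.57 ± 0.27 (adjusted p = 5.71e-06) and −1.18 ± 0.28 (adjusted p = 0.0152). FIT2 lost its call without wild-type replicate 1 (0.23) or 2 (0.119) and FIT3 with the length trend removed (0.745). The 2 higher genes, named after their values were seen, were SOM1, of the mitochondrial inner membrane peptidase, at 1.15 ± 0.27 (adjusted p = 0.00948) and YGR050C, of unknown function, at 29.7 against 13.3 RPKM (adjusted p = 0.0113). SOM1 lost its call without wild-type replicate 2 (adjusted p = 1), and YGR050C without wild-type replicate 1 (0.0788) or 2 (0.0718). Without wild-type replicate 1, 27 genes were called in all.

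Translational efficiency, the footprint change less the mRNA change, asked which genes were translated more or less per transcript. In can1 the arginine genes had the largest values among those named: ARG8 at 1.65 ± 0.36 (adjusted p = 0.573), CPA1 at 1.37 ± 0.27 (adjusted p = 0.299) and ARG56 at 0.95 ± 0.30 (adjusted p = 1). None of the 3 passed over all genes and all passed when adjusted over the list alone, where the median of the 9 genes was 0.53 (adjusted p = 0.632 with an estimated correlation). CPA1 passed over all genes without can1 footprint replicate 1 (1.53, adjusted p = 0.0494). GCN4 stood at 0.90 ± 0.34 (adjusted p = 1), and at 0.03 in rpl22a, where mRNA is 1 library. For the Msn2/Msn4 stress genes the median was −0.25 over 36 genes, with 0 past the threshold (camera adjusted p = 0.000497, or 0.632 with an estimated correlation), and it was −0.02 without can1 mRNA replicate 2. For the 95 ribosomal protein genes the median was 0.25 with 0 past the threshold (adjusted p = 0.636 with an estimated correlation), 0.07 with the deposited scaling, 0.07 without wild-type mRNA replicate 1 and 0.05 without can1 mRNA replicate 2. The deposited scaling moved the median of all genes by −0.18.

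Over 4879 genes limma called 1 gene in can1, the deleted CAN1 itself, whose reads are too few in can1 for a ratio, and voom called 0. In that limma fit 87 genes had an unadjusted p under 0.05, against 243.95 that chance alone would give. The test thus ran conservative, and the lack of calls does not show that efficiency was unchanged. In rpl22a limma called 0 genes and voom 11, with 705 at an unadjusted p under 0.05, and in tor1 both called 0, with 75. RPL22B stood at 0.81 ± 0.32 in rpl22a (adjusted p = 0.299). The ribosomal protein genes had a median of 0.73 in rpl22a, 0.43 with the length trend removed, and 0 of 95 passed (adjusted p = 0.89 with an estimated correlation). The Spearman correlation of the rpl22a change with coding length was −0.62. It was −0.42 in footprints and 0.26 in the single mRNA library, whose opposite trend enlarges the efficiency value. Camera called 11 lists in can1, between 3 and 18 with 1 library left out (3 without wild-type mRNA replicate 1 and 18 without wild-type mRNA replicate 2), 3 in rpl22a and 10 in tor1, and 0 in each with an estimated correlation. In simulated data 56.1% of genes with a 2-fold change in efficiency were called in can1 and 47.0% in rpl22a, so changes of that size were not all detectable at this depth and number of libraries.

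**Figure D4:**
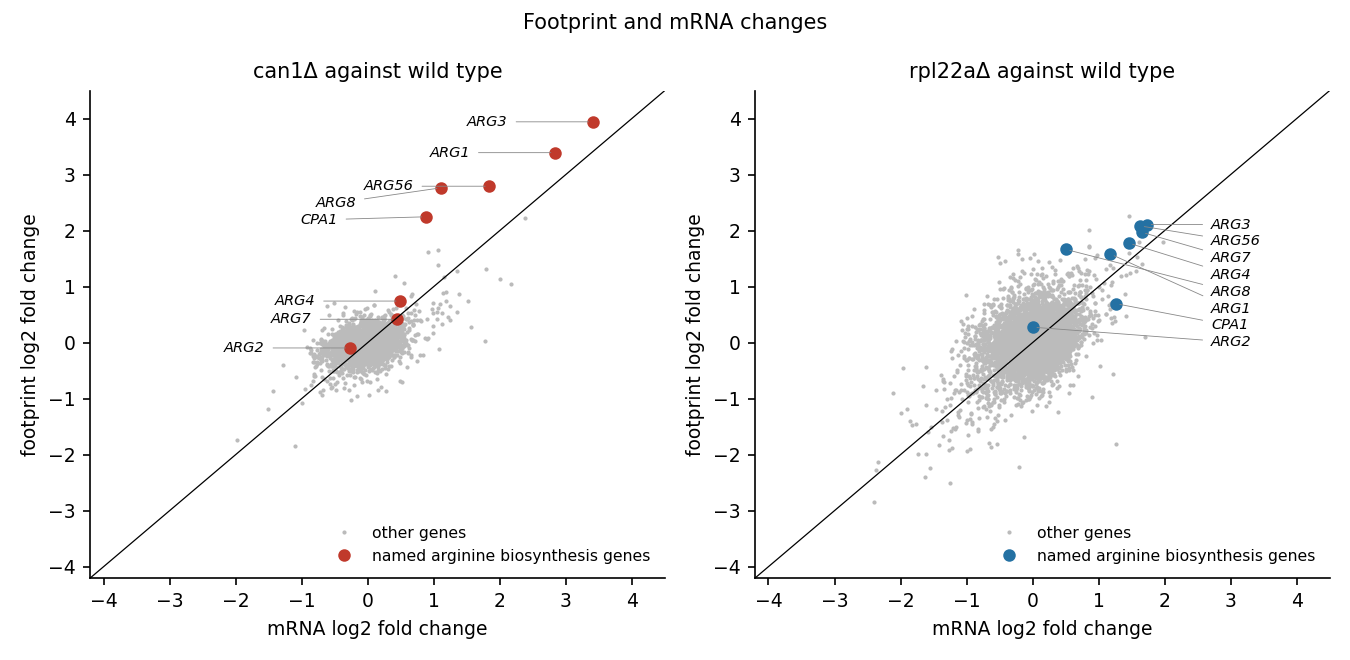
Log2 fold change against wild type in footprints (y axis) and in mRNA (x axis) for genes tested in both, with a panel for can1 and a panel for rpl22a, the deleted gene left out and named arginine genes in colour. ARG3 lies at 3.94 in footprints and 3.41 in mRNA in can1, and at 2.11 and 1.73 in rpl22a.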

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

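The tests of reads shared between libraries, of the length trend, of Gcn4 targets and of single libraries were chosen after the result was seen; the tests of genes with few reads, of ribosomal protein genes in the scaling and of other splits were written before.

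The deletion strains differed from each other by direct tests: 1162 genes between can1 and rpl22a footprints, 9 between can1 and tor1, and 720 between rpl22a and tor1. Fold changes in each followed coding length, with Spearman correlations of 0.48, 0.37 and −0.29. These differences between groups are what singled them out, and the genes are given in the report. Of the weighed patterns below, the first is a part of them.

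Arginine genes were higher in rpl22a as well as in can1 footprints. Reads from can1 libraries in the rpl22a libraries are argued against for 3 arginine genes, ARG7 and ARG4 among them. These lay past the threshold at a higher level in rpl22a than in can1. For the other arginine genes the level of RPL22A argues against it, since can1 reads would carry RPL22A reads with them. RPL22A had a mean of 9.95 RPKM in rpl22a footprints and 2834 in can1 footprints. The coding-length trend of the rpl22a libraries is argued against as the whole cause by its size. Its median shifts, 0.36 for short and −0.18 for long genes, are small beside the median rise of the arginine list. Removal of so small a trend could hardly undo the calls, and 8 of the 9 genes still passed in rpl22a. In rpl22a a rise of Gcn4 targets outside arginine synthesis was present, with 19 of 33 past the threshold, while a rise of the same size in can1 is argued against, since 15 of them were past the threshold and lower in can1 than in rpl22a. In can1 these targets had a median of 0.15 in footprints and 0.03 in mRNA, where 19 of 35 lay above 0. The unadjusted camera p of this set, at the preset correlation, was 0.722 in mRNA and 6.16e-09 in footprints. A Gcn4 response is thus a candidate explanation in rpl22a, and what raised the arginine genes in can1 stays open. GCN4 itself does not part the strains in this way. Its mean footprint level was 91.4 RPKM in can1, 96.6 in rpl22a and 65.1 in wild type. Its change in efficiency was 0.03 in rpl22a, with 1 mRNA library, and was larger in can1. Gcn4 protein and arginine were not measured.

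Footprints of short genes were higher and of long genes lower in rpl22a. Noise of genes with few reads is argued against, since the long minus short difference was −0.45 among genes of at least 20 CPM. Coding-length trends that differ between libraries of 1 strain cannot be told apart from an effect of the deletion: 1 of 2 rpl22a libraries lay outside the range of the other footprint libraries by more than the spread of wild type, and 2 libraries are too few to decide. An effect of the missing ribosomal protein on initiation by length may contribute and was not tested.

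In can1 the median over 95 ribosomal protein genes was −0.42 in mRNA and 0.25 in translational efficiency, with 1 and 0 genes past the threshold. Neither list kept its call with an estimated correlation (adjusted p = 0.841 and 0.636), so the pattern is one of medians. Of the 4 can1 and wild-type pairs of mRNA libraries 3 differed by −0.37, −0.85 and −0.47 and 1 by 0.0235, while libraries of the same strain differed by −0.47 and −0.39, as much as the strains did. The length trend is argued against as the whole cause, since the efficiency median was 0.25 after its removal, and so is the weight of ribosomal protein genes in the scaling (0.26 with factors computed without them). A difference between single libraries is thus a candidate explanation, and an effect of the deletion stays open.

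The 6 wild-type and can1 footprint libraries make 10 splits, too few for a share under 0.05. The real split called 11 genes and the highest of the others 27, so 2 of 10 called as many; for gene lists the real split called 16 and the highest other 12, so 1 of 10 did. The split that called 27 set wild-type replicates 1 and 2 with can1 replicate 1 against the rest. It points to a structure of the samples: this split also parts the deeper libraries (8.56, 5.16 and 8.70 against 2.52, 4.75 and 3.42 in units of 1e6 reads) and those with the smaller long minus short differences (−0.13, 0.18 and 0.02 against 0.34, 0.37 and 0.44), and which of these lies behind it was not tested. The 5 other splits that, like it, part 1 pair of equal numbers called 0 genes in limma. The 3 other splits that part all 3 pairs called 0 genes each in limma and 8, 4 and 8 lists.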

How the results depend on the processing

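The tests with other pseudocounts, the deposited scaling, moderation that was not robust, the length trend removed, and the block for wild type and can1 alone (also with the 2 strains only) were chosen after seeing the data; the others were planned. Over the counts of changed genes, 159 alternatives stayed within 1.5 times the count and 57 did not; over list counts 74 did and 28 did not. For named genes 2161 kept direction and side of the threshold, 102 lost the call, 13 gained it and 1 reversed. The cause was not tested except where fewer genes, samples or calls follow from the setting itself. The planned second count tool was not run. With the replicate block MTE1 in can1 footprints (adjusted p = 0.064), HEM13 in tor1 footprints (0.0893), ARO10 in can1 against tor1 (0.113) and CAN1 efficiency (0.056) lost their calls. With the block for wild type and can1 MTE1 lost it (0.0511) and BAT1 (0.0319) and BAT2 (0.0416) gained one, as they did with the length trend removed as well (0.0219 and 0.0414). With that block and the 2 strains only MTE1 lost it (0.0581) and BAT1 (0.0288), CAR1 (0.0398) and HCH1 (0.0085) gained one. Blocks changed no other call among named genes. Depth limits low genes: 10 reads in the median library were needed for a test. A lone library left in a group is assumed to vary like the others.

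In can1 footprints 17 genes were called with the block for wild type and can1, and 29 with the block and the 2 strains only. At least 2-fold were 175 genes in rpl22a footprints, 199 in can1 against rpl22a, 175 in rpl22a against tor1 and 42 in can1 mRNA. In tor1 footprints 1 gene was called with scaling without ribosomal protein genes, 1 with no filter, 5 at 20 CPM, 4 by voom, 1 with the 2 strains only, 1 with pseudocount 0.25, 5 with the deposited scaling and 1 without robust moderation. In can1 mRNA 29 were called with no filter, 18 at 20 CPM, 138 with the replicate block and 31 with the length trend removed. In rpl22a mRNA 103 were called with no filter, 106 at 20 CPM and 117 with the deposited scaling. In tor1 mRNA 2 were called at 20 CPM, 4 by voom, 6 with the deposited scaling, 8 without robust moderation and 7 with the length trend removed. For efficiency in can1, limma called 0 at 20 CPM, with the 2 strains only, with the replicate block and with pseudocount 0.25, and voom 0. In rpl22a voom called 11 and limma with pseudocount 4 called 1.

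With an estimated correlation camera called 2 lists in can1 footprints, 1 in can1 against tor1, and 0 in rpl22a and tor1 footprints, in the other direct comparisons, in all 3 mRNA and in all 3 efficiency comparisons. Fry called 23 lists in rpl22a footprints, 20 in can1 against rpl22a, 22 in rpl22a against tor1, 2 in can1 footprints, 2 in can1 against tor1, and 0 in tor1 footprints, in mRNA and in efficiency.

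With 1 library left out the counts ranged from 331 to 976 in rpl22a footprints, 1 to 9 in tor1 footprints, 387 to 1316 in can1 against rpl22a, 239 to 412 in rpl22a against tor1, 4 to 157 in can1 mRNA, 78 to 191 in rpl22a mRNA and 18 to 27 in tor1 mRNA. They ranged from 0 to 2 for efficiency in can1 and 0 to 3 in rpl22a, and for lists from 10 to 16 in can1 footprints and 3 to 18 for efficiency in can1. Ranges within 1.5 times were 8 to 15 in can1 footprints and 8 to 12 in can1 against tor1. With separate wild-type libraries the mean correlation between strains changed sign to −0.0378 for can1 and rpl22a (range −0.263 to 0.145) and −0.0701 for can1 and tor1 (−0.363 to 0.136), ranges that span 0. CAN1 efficiency in can1 reversed with voom to 0.00315, near the floor of its reads.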

Other observations

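The test of the 33 Gcn4 targets outside arginine synthesis as a set was chosen after the result was seen. Its p-values are for this set alone and are unadjusted, while those of the lists above were adjusted over all lists. They therefore cannot be set beside the adjusted p of the whole Gcn4 list. In can1 footprints their median log2 fold change was 0.15, with 27 above 0 and limma calling 0. Camera gave the set an unadjusted p of 6.16e-09, or 0.0156 with an estimated correlation. In rpl22a footprints the median was 0.46, with 29 above 0 and 19 called (p = 0.00938 with an estimated correlation). In can1 against rpl22a it was −0.35 (p = 0.0366 with an estimated correlation), and in tor1 footprints −0.03 (p = 0.546 with an estimated correlation). In mRNA the median over 35 such targets was 0.03 in can1, with 19 above 0 and limma calling 0 (p = 0.722, or 0.931 with an estimated correlation), and 0.51 in rpl22a, with 32 above 0 and 8 called (p = 0.221 with an estimated correlation).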
